A study of Homo sapiens with 4 samples.

How the data were processed

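Total RNA of CWR22Rv1 cells was labelled with biotin through an amplified cRNA and hybridised to Illumina bead arrays, per the labels' protocols, with 2 arrays of cells given the control vector pLKO.1 and 2 of cells given shJMJD1A. The authors deposited a table of probe intensity values that were not normalized, per the file headers, beside a detection p-value for each probe and array. The software, its version and any background step behind these intensity values are not given in the sources used here. The deposited detection p-value ranks a probe against negative control probes, and each p-value column was checked to belong to the signal at its left by a rank correlation of -0.982 to -0.99 between them. The authors also deposited processed values on a log2 scale for 25389 of the 47317 probes, which are exactly the probes with a detection p under 0.05 on at least 1 array. Each of these log2 columns correlated at 0.999 or more with the log2 intensity of its own array, so the scale is log2 and genes were not centred, while the authors' normalization method stays unknown. The medians of the deposited log2 columns were 8.30 and 8.29 for pLKO.1 and 8.22 and 8.23 for shJMJD1A, and the columns were used as an alternative. Columns were assigned to samples by the sample number in the labels.

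Background was corrected with limma 3.58.1 in R 4.3.3 by the normal-exponential convolution model, with the moments of the negative controls inferred from the detection p-values and an offset of 16, and log2 values were quantile normalized. A probe entered the test with a detection p under 0.01 on at least 2 of the 4 arrays. Probes were named from GEO's platform annotation, which covers the probes of the authors' processed table, with symbols updated by gene identifier through a RefSeq table of assembly GRCh38.p14 that was used for names, RNA classes and neighbouring genes only. Of the 25389 probes, 18438 had 1 gene symbol, 4 had several and 6947 had none here, and 18423 had an identifier that matched the RefSeq table. Of 18171 probes past the filter, 14499 had 1 symbol, and the probe with the highest mean signal stood for each of the 10984 genes. The brightest probe can miss a change that other probes of the gene show, and the mean of all detected probes was an alternative.

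Differences were tested in limma with lmFit and eBayes, shJMJD1A minus pLKO.1, without a replicate block, and adjusted by Benjamini-Hochberg over all genes tested at a threshold of 0.05. All tests are two-sided. A probe with no detection p under 0.01 in a group has only a bound there. Its fold is given as "at least", from the mean of the brighter group to the mean, over the dimmer group's arrays, of the higher of the lowest signal among detected probes and the probe's own signal. This gave 141 genes a bound in pLKO.1 and 276 in shJMJD1A. Background correction widens the folds of dim probes and bright probes are compressed, so fold sizes depend on the signal level. The median log2 fold change of all genes was 0.04.

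Before the data were examined, 30 gene lists, the comparison, the processing alternatives and the rule for named genes were fixed. Lists with at least 5 measured members were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, and adjusted over the 29 lists tested. With 4 arrays an estimated correlation leaves camera few degrees of freedom, so a list that fails there is not thereby argued against. Named were KDM3A, KDM3B, JMJD1C, MYC and KLK3 whatever their result, the 12 genes with the largest rise and the 12 with the largest fall among those past the threshold with no overlap between groups, and up to 4 members of smallest p in each list. A further gene and 3 of the lists are not reported here. Members with other results were named only where the text says that they were chosen after their values were seen.

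The procedure was tested on simulated arrays built on the real mean signals, in which 10920 genes were tested. It called 0 of 67 genes changed by 0.5 on the log2 scale, 12 of 66 changed by 1 (18.2%), 54 of 65 changed by 2 (83.1%) and 2 of 10722 unchanged genes. The simulated spread was drawn from the limma fit, with noise added at the SD of all signals with a detection p of 0.05 or more. Background noise was thus counted more than once, so these shares are not the power on the real arrays. Few genes were changed in this simulation, and the adjusted threshold is easier to pass where many are. In a simulation of gene lists, 5 of 5 shifted and 0 of 25 unshifted lists were called. There genes varied independently, all members of a shifted list moved by the same amount and few other genes changed. It therefore does not give the power or the error rate for the real lists.

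The alternatives were no background correction, a normal-exponential model on the signals alone with an offset of 50, median scaling over detected probes, cyclic loess, the authors' values, no detection filter, detection on all 4 arrays, the mean of a gene's probes, an intensity trend with a robust prior, the replicate number as a block, each array left out in turn, a 2-fold threshold and the estimated correlation. Median scaling over all probes was added after the data were seen. Where an array was left out, normalization and genes were kept, and the lone array of its group was taken to vary like the other group. The labels and files give no slide or scan date, so no batch was tested. The 3672 detected probes without a single symbol were left out of the comparison.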

Results

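Gene expression was measured in CWR22Rv1 cells, an established line of human prostate cancer, after lentiviral delivery of a short hairpin against JMJD1A or of the hairpin vector pLKO.1 as control. JMJD1A, whose current symbol is KDM3A, is a histone demethylase that removes methyl groups from lysine 9 of histone H3. RNA was taken 48 h after transduction and hybridised to Illumina bead arrays, with 2 arrays for shJMJD1A and 2 for pLKO.1. Between 17452 and 17970 of the 47317 probes on each array were detected, and the median signals were 183 and 168.1 on the pLKO.1 arrays and 169.9 and 161.3 on the shJMJD1A arrays. The small number of arrays limits the precision of every value. The labels do not say that the replicates were separate cultures, so the p-values measure the spread between these samples, which may be technical.

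The targeted transcript was lower in both knockdown samples. KDM3A fell by 1.70 on the log2 scale (SE 0.148, adjusted p = 0.00184 in limma), from a mean log2 signal of 8.41 ± 0.21 (SD, n = 2) to 6.71 ± 0.10 (SD, n = 2), which is 3.25-fold. Its paralogue KDM3B fell by 0.57 (SE 0.111, adjusted p = 0.0138 in limma), and for the related JMJD1C the log2 fold change was 0.09 (SE 0.143, adjusted p = 0.65 in limma). KDM3A was read by 1 probe, and its fall was 0.96 without background correction. The call on KDM3B ended when any 1 of the 4 arrays was left out, with falls of 0.56 to 0.59.

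The series asks how JMJD1A bears on the expression of MYC, the transcription factor that drives growth and ribosome production. MYC fell by 0.86 on the log2 scale (SE 0.114, adjusted p = 0.0049 in limma), from 12.97 ± 0.05 to 12.10 ± 0.06 (SD, n = 2 each), which is 1.82-fold. Its second detected probe gave a log2 fold change of -1.04. Among the MYC family and its partners, 4 of 13 measured genes rose and 4 fell, including rises of FBXW7 by 0.92, which encodes a ubiquitin ligase subunit that targets MYC, and of MNT by 0.83, a repressor that competes with MYC. Adjusted over the list alone, 5 rose and 5 fell.

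**Figure D1:**
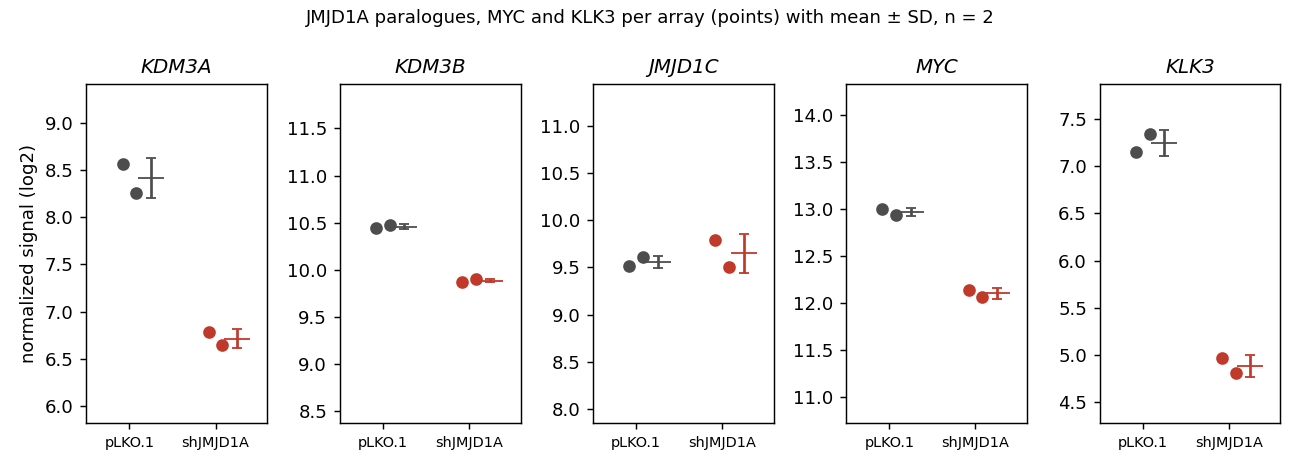
Normalized log2 signal of KDM3A, KDM3B, JMJD1C, MYC and KLK3 in a panel each, with a point per array for pLKO.1 (grey) and shJMJD1A (red) and the mean ± SD of the 2 arrays beside them. Every panel spans the same log2 range, and the groups lie apart for KDM3A, KDM3B, MYC and KLK3, with a log2 fold change of -1.70 for KDM3A and -0.86 for MYC.

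Known MYC targets went both ways, beside 4020 of all 10984 genes tested that changed. Of 43 measured targets, 9 fell, 3 rose and 31 did not pass the test, and adjusted over the list alone 5 fell and 3 rose. EXOSC5, a subunit of the RNA exosome, fell by 1.53 and NOLC1, a nucleolar phosphoprotein, by 0.93. Those that rose were MCM5 of the replicative helicase, the spermidine synthase gene SRM and RRP12, named after their values were seen. The list was not past the threshold against other genes (camera adjusted p = 0.813, and adjusted p = 0.919 with an estimated correlation), and its median of 0.02, mean of -0.06 and downward camera test differed in sign.

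Across the genome, shJMJD1A changed the level of 4020 of 10984 genes tested with limma, 2042 higher and 1978 lower. Of these, 424 were higher and 636 lower by at least 2-fold. The changed genes are 36.6% of those tested, and each list's count of called members stands beside that share. A count near or below it shows no excess of changed members in a list. The groups did not overlap for 7975 of the genes tested (72.6%), where chance gives 33.3%. The SD of the log2 difference between arrays was 0.276 within pLKO.1 and 0.282 within shJMJD1A, and 0.650 to 0.665 between the groups. With any 1 array left out, 1999 to 2345 genes passed.

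Among the largest rises, CGA, the common alpha subunit of the glycoprotein hormones, rose by 2.96 (SE 0.163, adjusted p = 0.000926 in limma), and CACNB2, a subunit of voltage-gated calcium channels, rose by 2.95 (SE 0.166, adjusted p = 0.000926 in limma). A2M, a plasma protease inhibitor, rose by 2.87, PGM2L1 by 2.86, the lipid raft gene RFTN1 by 2.77, the activin-binding protein gene FST by 2.44 and the AP-1 subunit gene FOSB by 2.49. MMP10, a matrix metalloproteinase, was not above background in pLKO.1 and was at least 5.58-fold higher in shJMJD1A (adjusted p = 0.000812 in limma). HS6ST2, which encodes a heparan sulfate sulfotransferase, was at least 5.16-fold higher, CNTNAP2 at least 2.94-fold and the endolysosomal channel gene TPCN1 at least 2.70-fold. CHRM3, a muscarinic acetylcholine receptor gene detected on 1 of the 2 pLKO.1 arrays, rose by 2.70. Sizes were smaller without background correction, where PGM2L1 rose by 1.77, CHRM3 by 1.52 and FOSB by 1.48. CACNB2, CHRM3 and FST were higher on a second detected probe too, and the other genes named here were each read by 1 probe.

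Among changed genes above background in both groups, the falls reached further than the rises. KRT19, a keratin of simple epithelia, fell by 5.16 (SE 0.115, adjusted p = 0.000278 in limma), which is 35.8-fold, and stayed above background in both groups. SLC26A3, which encodes a chloride and bicarbonate exchanger, was not above background in shJMJD1A and was at least 27.6-fold lower (adjusted p = 0.000812 in limma). FABP7, a fatty acid-binding protein gene, fell by 3.63, and the imprinted gene SNRPN fell by 3.18 on its brightest probe and was lower on its other 2 detected probes. TMPRSS2, a serine protease gene, fell by 3.13, GPER1, a G protein-coupled estrogen receptor gene, fell by 3.02, and PMEPA1 fell by 2.89. KLK3, which encodes prostate-specific antigen, was not above background in shJMJD1A and was at least 1.95-fold lower. C9orf152 was at least 6.49-fold lower, the sialyltransferase gene ST6GAL1 at least 6.54-fold and GLYATL2 at least 3.05-fold. The growth hormone receptor gene GHR fell by 3.42 and MOCS2, which encodes molybdopterin synthase subunits, fell by 2.93, both detected on 1 of the 2 shJMJD1A arrays. Without background correction SLC26A3 fell by 3.54, GHR by 2.08 and MOCS2 by 1.81 on the log2 scale. GPER1, PMEPA1 and MOCS2 were lower on their other detected probes too. KRT19, SLC26A3, FABP7, TMPRSS2, KLK3, C9orf152, ST6GAL1, GLYATL2 and GHR were each read by 1 probe.

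**Figure D2:**
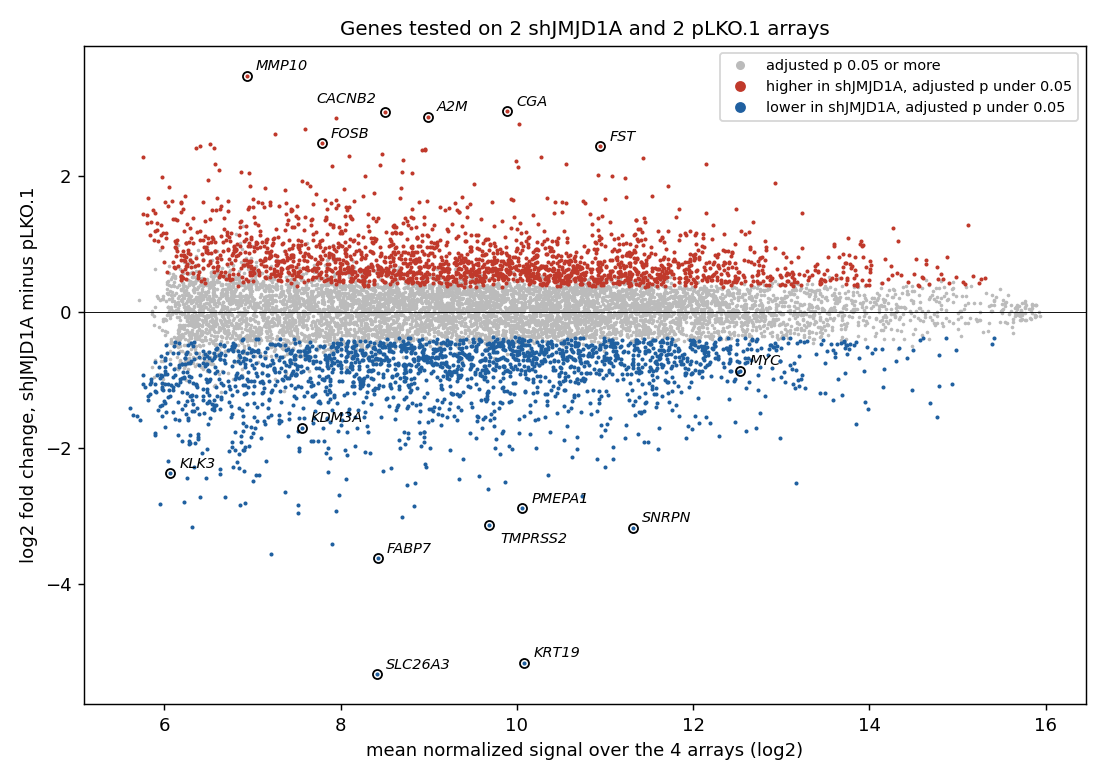
Log2 fold change of each gene tested, shJMJD1A minus pLKO.1, against its mean normalized log2 signal over the 4 arrays, coloured by the adjusted p of limma. Genes past the threshold lie on both sides at all but the brightest signals, and KRT19, at a log2 fold change of -5.16, and SLC26A3, not above background in shJMJD1A and so only bounded, lie apart from the rest at the bottom.

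Of 24 measured immediate early genes, 8 rose, none fell and 16 did not pass the test, over all genes and adjusted over the list alone, with EGR1 higher by 2.00, DUSP4 by 1.63, FOS by 1.54 and FOSB by 2.49. The list passed the threshold in camera (adjusted p = 0.0439) but not with an estimated correlation (adjusted p = 0.745). Its adjusted p was 0.0515 without pLKO.1 replicate 1, 0.0646 without shJMJD1A replicate 2 and 0.0895 among genes detected on all 4 arrays.

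Of 11 measured histone genes, 6 rose, none fell and 5 did not pass the test, and adjusted over the list alone 6 rose and 1 fell. H2BC21 rose by 1.85, H2AC6 by 1.54 and H2BC12 by 1.45, and H2AC8 was not above background in pLKO.1 and at least 1.32-fold higher in shJMJD1A. Of 90 structural RNAs, small noncoding RNAs with 3 ribosomal RNAs, which like many histone messages lack a poly(A) tail, 28 rose, 7 fell and 55 did not pass the test, beside 2042 and 1978 of the 10984 genes. This class was examined after 8 of its members had been seen to rise, among them RNU4-1, a spliceosomal RNA, by 2.41 and RPPH1, the RNase P RNA, by 1.40. The histone list passed the threshold in camera (adjusted p = 0.0439) but not with an estimated correlation (adjusted p = 0.745). With any 1 array left out its adjusted p was 0.0515 to 0.0799, and it was 0.0895 among genes detected on all 4 arrays.

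No gene of the interferon response rose: of 21 measured, 8 fell, the same number as adjusted over the list alone. HERC5, the ligase for the ubiquitin-like ISG15, fell by 0.90 and MX1, an antiviral GTPase gene, by 0.82. The camera adjusted p was 0.0609, and it was 0.745 with an estimated correlation. It lay between 0.0399 and 0.0498 with median scaling, with a replicate block, in the authors' values and without the detection filter, and between 0.0585 and 0.123 with 1 array left out. Among sensors of foreign nucleic acid, restriction factors and the RNA interference machinery, 4 of 9 rose and 1 fell, the same as adjusted over the list alone, with AGO2, the slicing Argonaute, higher by 1.06 and DICER1, which cuts hairpin precursors, higher by 0.92 (camera adjusted p = 0.401). Of 9 inflammatory and NF-kB genes, 3 rose and 1 fell, again the same adjusted over the list alone: PTGS2, an inducible cyclooxygenase, rose by 1.65, RELB by 1.45 and NFKB2 by 1.26 (camera adjusted p = 0.401). RELB rose by 0.77 without background correction.

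**Figure D3:**
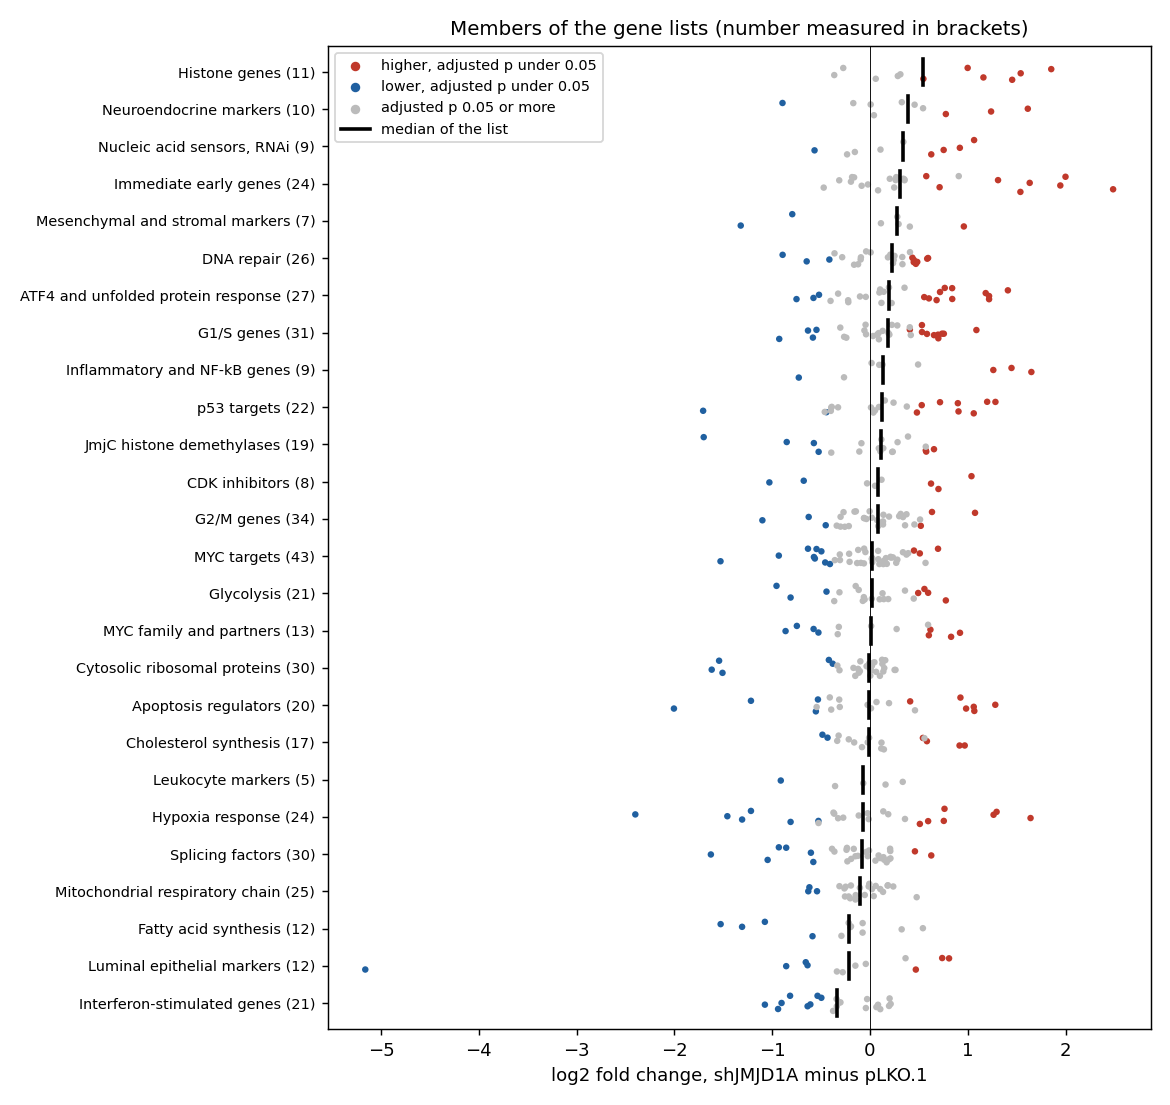
Log2 fold change of each measured member of the 26 gene lists reported here with at least 5 measured genes, shJMJD1A minus pLKO.1, with a black line at each list's median and colours for the adjusted p of limma. The median of the interferon-stimulated genes lies lowest at -0.34 and that of the histone genes highest at 0.55, and most medians lie near 0. The histone median was 0.41 with bounds in place of values below background, and 0.30 both without background correction and in the authors' values.

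Of 27 genes of the ATF4 and unfolded protein response, 11 rose and 3 fell (12 and 3 adjusted over the list alone), with the chaperone genes DNAJB9 higher by 1.41 and HSPA5 by 1.22 and the degradation factor gene EDEM1 by 0.84 (camera adjusted p = 0.164). Of 12 fatty acid synthesis genes, 4 fell and none rose, over all genes and adjusted over the list alone: ACLY, which makes cytosolic acetyl-CoA, fell by 1.53, the elongase gene ELOVL6 by 1.31 and the regulator SREBF1 by 1.07 (camera adjusted p = 0.125). Of 17 cholesterol synthesis genes, 4 rose and 2 fell (5 and 2 adjusted over the list alone), DHCR7 by 0.92 upward (camera adjusted p = 0.925). Of 24 hypoxia genes, 7 rose and 6 fell (7 and 8 adjusted over the list alone), with CA12, a carbonic anhydrase gene, lower by 2.40 and P4HA2, a collagen prolyl hydroxylase gene, higher by 1.26 (camera adjusted p = 0.819). Of 21 glycolysis genes, 4 rose and 3 fell, the same as adjusted over the list alone (camera adjusted p = 0.925). Of 25 respiratory chain genes, 3 fell and 22 did not pass the test, as adjusted over the list alone (camera adjusted p = 0.401).

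Cell cycle genes went both ways, in a comparison that called 36.6% of all genes tested. Of 31 G1/S genes, 10 rose and 4 fell (11 and 4 adjusted over the list alone), CDC25A, a phosphatase that activates cyclin-dependent kinases, by 1.09 upward (camera adjusted p = 0.38). Of 34 G2/M genes, 3 rose and 3 fell (3 and 2 adjusted over the list alone), the transcription factor gene FOXM1 by 1.07 upward and the spindle checkpoint gene MAD2L1 by 1.10 downward (camera adjusted p = 0.925). Of 8 genes in the list of inhibitors of cyclin-dependent kinases, 3 rose and 2 fell, the same as adjusted over the list alone. The list also holds RB1, RBL2 and CDKN3, which are not such inhibitors in the strict sense, and CDKN3 is among the 3 that rose. CDKN2B was higher by 1.04 and CDKN1B fell by 1.03 (camera adjusted p = 0.819 for the list). CDKN2B rose by 0.49 and FOXM1 by 0.70 without background correction.

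Of 22 p53 targets, 8 rose and 2 fell, the same as adjusted over the list alone, with the cytokine gene GDF15 higher by 1.28 and the death receptor gene TNFRSF10B by 0.90, while CCNG1 fell by 1.71 (camera adjusted p = 0.527). Of 20 apoptosis regulators, 6 rose and 4 fell (7 and 4 adjusted over the list alone): BAK1, a pore-forming effector, rose by 1.28, and BIK and BNIP3L, of the BH3-only class, fell by 2.00 and 1.22 (camera adjusted p = 0.925). Of 26 DNA repair genes, 7 rose and 3 fell, the same as adjusted over the list alone (camera adjusted p = 0.768). BAK1 rose by 0.74 and BIK fell by 1.12 without background correction.

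Of 30 splicing factors, 6 fell and 2 rose, the same as adjusted over the list alone, with SRSF7 lower by 1.05 and the epithelial regulator ESRP1 by 0.86 (camera adjusted p = 0.401). Of 30 cytosolic ribosomal protein genes, 5 fell and none rose (3 and none adjusted over the list alone), RPL24 by 1.54 and RPL13 by 1.62 (camera adjusted p = 0.401). With the mean of its probes in place of the brightest, RPL13 fell by 0.86. Of 19 histone demethylases, JmjC or related, 3 rose and 4 fell, the same as adjusted over the list alone, with KDM1A, a flavin-dependent demethylase, lower by 0.85 (camera adjusted p = 0.925).

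Cell type markers went in both directions. Of 12 luminal epithelial markers, 3 rose and 4 fell (3 and 5 adjusted over the list alone): KRT18 rose by 0.74, the epithelial factor gene ELF3 by 0.81, and KRT19 fell by 5.16 (camera adjusted p = 0.527). Of 10 neuroendocrine markers, 3 rose and 1 fell (4 and 1 adjusted over the list alone), with the transcription factor gene ONECUT2 higher by 1.24, SOX2 not above background in pLKO.1 and at least 1.54-fold higher, and TUBB3 lower by 0.89 (camera adjusted p = 0.401). Of 7 mesenchymal and stromal markers, 1 rose and 2 fell (2 and 2 adjusted over the list alone), VIM, the vimentin gene, by 1.32 downward and TAGLN by 0.96 upward (camera adjusted p = 0.925). Of 5 leukocyte markers, HLA-DRA fell by 0.91, as adjusted over the list alone, and the other 4 did not pass the test (camera adjusted p = 0.844), and with the mean of its probes the call on HLA-DRA ended at a log2 fold change of -0.51. Of the basal epithelial markers 2 were measured, too few for a list test, and CD44 fell by 0.89.

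In all, 29 lists were tested and 26 are reported. Of these 2 passed an adjusted p of 0.05 in camera and none with an estimated correlation, where the lowest adjusted p was 0.745. In fry, which asks whether the genes of a list move one way on balance without comparing them with other genes, 11 of the 26 passed. Camera and fry gave opposite signs for the demethylases and the mesenchymal markers, where median and mean also differed in sign, as they did for cholesterol synthesis and apoptosis regulators. The sign of the median differed between scalings for MYC targets, the MYC family, apoptosis, cholesterol synthesis, glycolysis, splicing, ribosomal proteins and the respiratory chain.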

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

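Of the 3672 detected probes that were left out of the comparison for want of a single gene symbol, 597 differed between shJMJD1A and pLKO.1 in limma at an adjusted p under 0.05, 256 higher and 341 lower. They are given here because they are a signal in data that no comparison of named genes used. They make up 16.3% of those probes, against 36.6% of the named genes, and 264 of them differed by at least 2-fold. The shares come from separate fits and adjustments, over every unnamed probe and over the brightest probe of each named gene. They therefore do not compare like with like. What these probes measure was not analysed here.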

How the results depend on the processing

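The test with median scaling over all probes was chosen after the data were seen, and the others before. KDM3A and MYC were lower past the threshold under every alternative that was run on single genes, and 2783 (no detection filter) to 4954 (intensity trend and robust prior) genes changed under those that keep the 4 arrays and the threshold. Without the detection filter 1325 genes were higher, where 13560 genes were tested. With a 2-fold threshold 1060 genes changed, 424 higher and 636 lower, fewer by construction, and MYC, at 1.82-fold, was not among them. With 1 array left out, 1999 to 2345 changed, 954 to 1112 higher and 1045 to 1290 lower, on fewer arrays, and of these 1900 to 2200 were shared with the main calls, in the same direction. With the replicate number as a block 4089 changed, 3794 of them shared. The deviations of the replicate 1 arrays from their group means correlated at 0.0655 over genes between pLKO.1 and shJMJD1A. With 2 arrays per group those of replicate 2 only mirror them. Whether same-numbered arrays shared a culture, slide or day is not shown by this. The block ended the call on RPL14 and brought NDUFB8 and the interferon list past the threshold, but other alternatives did so too. The call on RPL14 also ended with either median scaling, without the detection filter and with the mean of its probes. NDUFB8 also passed without background correction, with median scaling over detected probes and in the authors' values, among others. For the interferon list the camera adjusted p with the block was 0.042, but 0.745 with an estimated correlation and no block. The MYC targets passed under none of 16. JMJD1C, not past the threshold, was at -0.055 to 0.24 with 1 array left out, lowest without shJMJD1A replicate 1. List tests that turned direction were all far from the threshold, and the cause was not tested: the demethylases at adjusted p = 0.969 without background correction, 0.972 with median scaling over detected probes, 0.917 in the authors' values, 0.997 with detection on all 4 arrays, 0.948 with the intensity trend, 0.923 without pLKO.1 replicate 2 (0.83 to 0.971 with 1 array left out) and 0.971 with median scaling over all probes; apoptosis regulators at 0.971 with that scaling and without shJMJD1A replicate 1 (0.849 to 0.980); G2/M genes at 0.971 without that array (0.753 to 0.971); cholesterol synthesis at 0.938 without pLKO.1 replicate 2 (0.708 to 0.971); and leukocyte markers at 0.996 with the mean of probes. Genes near the background have the least certain sizes.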

Other observations

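The tests of array scale were chosen only after the result was seen, and so were the genes named here outside the fixed rule and the lists of lysosomal and imprinted genes. Several lysosomal genes were seen to rise in shJMJD1A. The peptidase gene TPP1 rose by 1.66, CTSK, a cathepsin gene, by 1.74, the phosphatase gene ACP2 by 1.40, the sphingomyelinase gene SMPD1 by 1.40 and the fucosidase gene FUCA1 by 1.40, while LIPA, the lysosomal lipase gene, fell by 2.09. Of 42 further lysosomal genes whose values had not been seen, 20 rose, 1 fell and 21 did not pass the limma test, and adjusted over the list alone 25 rose and 1 fell. Among them GLA, an alpha-galactosidase gene, rose by 1.35, the sialidase gene NEU1 by 1.28, the cathepsin gene CTSD by 1.01 and NPC1, a cholesterol transporter gene, by 1.01, while ATP6V0D1, a subunit of the proton pump, fell by 0.78. Their median of 0.43 lay above the -0.10 to 0.21 that held 95% of 10000 random lists matched on mean signal, and it was 0.40 in the authors' values. The bar set beforehand for a rise of lysosomal genes as a class was met (camera p = 1.80e-06, and p = 0.0351 with an estimated correlation). Both p-values are unadjusted, since this list was tested alone and not among the lists fixed beforehand. The list was drawn up after other lysosomal genes had been seen to rise on these same arrays, so it is not independent support.

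Of the glucuronosyltransferase genes of the UGT2B family, UGT2B28 rose by 2.19, UGT2B11 by 1.32, UGT2B10 by 0.52 and UGT2B17 by 0.40. UGT2B4, not above background in pLKO.1, was at least 1.66-fold higher, and UGT2B15 did not pass the test. The family was not tested as a list, nor was cross-reaction of probes between its near-identical genes. The orphan nuclear receptor gene NR4A2 rose by 2.40 and the heme oxygenase gene HMOX1 by 2.38. At the imprinted Prader-Willi locus SNRPN fell by 3.18 and SNURF by 2.71 while MKRN3 rose by 1.21. MEST, not above background in shJMJD1A, was at least 2.71-fold lower, SGCE fell by 1.37, and PEG10 rose by 0.93 and PHLDA2 by 0.94. Whether imprinted genes shift as a class stays open: of 20 without SNRPN and SNURF, 6 rose and 3 fell, and their median of 0.22 lay within the -0.24 to 0.30 of matched random lists, but its bootstrap 95% interval of -0.033 to 0.54 did not. The bound set beforehand took no account of that interval, so meeting it excludes nothing. In limma, camera on this list alone gave an adjusted p = 0.206, the same as its unadjusted value since no other list was in the family.

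The 22 dimmer MYC targets had a median of 0.021, with a bootstrap 95% interval of -0.295 to 0.21. It lay only just above the -0.3 set beforehand for falls hidden by compression of bright probes. With the mean of all detected probes per gene, the median of the MYC targets had an interval of -0.21 to 0.12, also above -0.3. Their camera adjusted p was then 0.823. That median, 0.021, was the same as with the brightest probe. A target with 1 detected probe keeps its value there, so the choice of probe was tested only for targets with several.

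KRT19 fell by 5.16 on the log2 scale within 48 h, and SLC26A3, not above background in shJMJD1A, was at least 27.6-fold lower. Each was read by 1 probe. A subline with other chromosome copy numbers in 1 group was looked for in windows of 50 consecutive tested genes. The largest absolute median was 0.33, under the 0.4 set beforehand, and 24.6% of 1000 shuffles of the genes reached as much. Of 991 windows, which overlap, 8 exceeded 0.3. These values argue against a shift of 0.4 or more over such a window. Array compression lowers such medians, so the gain or loss of 1 copy could stay under 0.4. Such a subline, changes over fewer genes and a subline of like copy number stay open. Background correction as the sole source is argued against, since without it the smallest of the 12 largest falls was -1.46 and KRT19 fell by 4.34. It did widen the falls, whose median was -3.17 with it and -2.33 without. SLC26A3 fell by 3.54 without it, so the bound of 27.6-fold holds for background-corrected signals only. A biological effect of JMJD1A or of the hairpin on these genes stays open and was not tested.

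Beside the 6 histone genes that rose, 8 structural RNAs were seen to rise, with a median of 1.56. Brighter shJMJD1A arrays were considered as a source. In signals that were not normalized the highest of the 4 array pairings' medians over all genes was 0.083, and the lowest median of these RNAs was 0.89. These RNAs were chosen because they rose after normalization, which already removes array scale. The gap thus follows from their choice and decides nothing. The lowest median of the histone genes, 0.054, was no higher than the highest of all genes. It comes from another pairing, and within each pairing, where a scale of the whole array cancels, the histone genes lay 0.248 to 0.46 above all genes. This comparison was made after the first had not decided and restates the rise of the histone genes that prompted it, so it does not decide either. The difference of 0.29 between the groups had a bootstrap 95% interval of 0.0068 to 1.18 over 11 genes. Better labelling or carry-over of RNA without a poly(A) tail could raise both: of the other 82 structural RNAs, small noncoding RNAs with 2 ribosomal RNAs, 20 rose and 7 fell, but their median of 0.13 lay at percentile 87.1 of matched random lists, which leaves it open. Among these RN7SK rose by 1.05 and the ribosomal RNA gene RNA28SN5 by 1.24. No biological explanation was tested.

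Genes next to each other among the tested genes of a chromosome changed alike more than by chance, though many pairs did not. Genes that were not tested can lie between the members of a pair, and no limit was set on their distance. Over 10401 adjacent pairs whose symbols do not share 3 letters the mean product of scaled fold changes was 0.0624, above the central 95% of 1000 shuffles within chromosomes, which reached 0.0274. Of all 139 adjacent pairs in which both genes changed by at least 2-fold, 86 changed in the same direction and 53 in opposite ones. The share expected by chance was not worked out for these pairs, and they include related genes such as STEAP1 and STEAP2. The rule on 3 shared letters also leaves in pairs such as SNRPN and SNURF or H2BC21 and H2AC20. SNPH and SDCBP2 rose by 2.24 and 2.15 and IGFBP3 and TNS3 fell by 1.86 and 2.45, while MOCS2 fell by 2.93 and its neighbour FST rose by 2.44. For pairs that lie close, transcripts that run from one gene into the next, shared promoters and local chromatin could each give this. They were not told apart by any test, and the distances within pairs were not examined. All values come from 1 hairpin, so effects of its sequence on other transcripts stay open and untested.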
